A study of Homo sapiens with 192 samples.

How the data were processed

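The data were probe counts from TempO-Seq, a targeted assay in which pairs of detector oligonucleotides are ligated on RNA in a cell lysate and sequenced, without RNA extraction. The cells were VM7Luc4E2, a sub-clone of the MCF-7 breast adenocarcinoma line that carries a stable estrogen receptor reporter. Per the labels' protocols, medium was conditioned for 2 h under lids that carried alginate hydrogels, a method called alginate immobilization of metabolic enzymes (AIME), and estrogen-stripped cells were then exposed to the conditioned medium for 24 h. The hydrogels held either hepatic rat S9, a liver fraction with cytosolic and microsomal enzymes (called "with S9" here), or deionized water ("without S9"). Per the labels' protocols, cofactors for oxidation and conjugation were in the medium of all wells. The treatment field of the DMSO wells gives 0.5% DMSO, while the protocol gives 0.1%, and the sources used here do not settle which held.

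The deposited values were whole-number counts per probe, one column per well, with no normalization by the authors. Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 and handled with SAMtools 1.9, and the alignment settings were not given in the sources used here. All 192 columns matched a labelled well. The table held 22533 probes of 50 nucleotides for 19683 gene symbols, 2211 of them with several probes. Gene names were read from the probe names after mending punctuation in 451 of them and 3 symbols that had been turned into dates. Each probe sequence was searched in the GENCODE transcripts of genome build GRCh38, where 22386 probes matched a transcript and 1623 matched transcripts of more than 1 gene. The probe list gives a fold attenuation above 1 for 869 probes, while the protocol calls the assay unattenuated. Attenuation would lower a probe's count by the same factor in every well.

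The design had 52 groups on 6 plates, 3 per condition, and each plate held a single condition, so a comparison of conditions in DMSO wells rests on 3 plates against 3. Plates 1 and 2 of a condition had all 32 treatments at the same positions, while plate 3 shared 1 (with S9) or 2 (without S9) with them, so plates 1 and 2 are not independent of well position. A plate with S9 and a plate without S9 had 1 to 6 of 32 treatments at the same positions. A difference between conditions thus also compares different well positions. Each plate had 5 DMSO wells, 3 wells of 17β-estradiol (E2) at 0.0001 µM, and 1 well of each of 8 concentrations (0.001 to 100 µM) of trans-stilbene, ethylparaben and daidzein. Totals ran from 955507 to 12268308 counts per well, with a median of 8154775. The labels flag 2 wells as LOW_NSIG80, daidzein at 3.73 and 100 µM on plate 1 without S9. Their totals were 955507 and 1440174 counts. Daidzein at 0.093 µM on plate 3 with S9, at 1536834 counts, had no flag and was kept. The 2 flagged wells were left out, which left 190 wells and n = 2 in both groups.

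Differential expression was tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1, version 1.17.8 of the data.table package) in 1 quasi-likelihood fit of all 190 wells, with a term for each of the 6 plates and 50 treatment effects, so that each effect was measured against the DMSO wells of the same plates. Counts were scaled by TMM. Probes were kept by filterByExpr at its default minimum of 10 counts, which left 20435. The negative binomial dispersion followed a trend over abundance, from 30 bins of 100 probes. A common dispersion was used at first. It gave too many false calls at low counts in simulated data and was replaced after results under it had been seen, so it is given among the alternatives. P-values were two-sided, adjusted by the Benjamini-Hochberg method within each comparison, and called at an adjusted p under 0.05. Standard errors (SE) were the size of the log2 change divided by the square root of F. The effect of a chemical with S9 minus that without S9 was tested in the same fit, for E2 as 1 contrast and for each other chemical as a joint test over its 8 concentrations. S9 against water in DMSO wells was tested on counts summed per plate, 3 plates against 3.

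Values per gene are CPM, counts relative to the TMM-scaled library size, with the standard deviation (SD) over wells. The estrogen receptor (ER) score was the mean log2 CPM, with a prior count of 2, of 30 estrogen-induced genes, relative to the DMSO wells of the same plate, with the SD over plates. It was tested with a two-sided exact permutation test within plates, adjusted over all chemical groups, and the difference between conditions with a two-sided exact permutation test of plates. The genes named for each comparison were up to 10 per direction with the largest change, 1 probe per gene, an adjusted p under 0.05, the same sign in every plate and a mean of at least 5 CPM in either group. A gene that met this rule for E2 without S9 is not reported here. Members of the gene lists and genes of the estrogen response outside this rule were chosen after their values were seen, except as list members.

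Lists fixed beforehand, 16 for pathways and 5 for cell types, were tested on log2 CPM with camera, which compares a list with the other genes, at a preset correlation of 0.01 and again with an estimated one, and with fry, whose PValue tests whether a list moves on balance one way and whose Mixed PValue tests change in either direction. Neither fry test compares a list with other genes. The lists covered estrogen-induced and estrogen-repressed genes, targets of AhR, NRF2, ATF4, p53 and the glucocorticoid receptor, endoplasmic reticulum stress, heat shock, mitosis, DNA replication, cholesterol synthesis, metallothioneins, hypoxia and glycolysis, interferon and NF-kB. The cell-type lists covered luminal and basal breast, hepatocyte, fibroblast and immune markers. Comparisons, tests, lists, the rule for named genes and 18 alternatives were chosen before the data were examined. They included DESeq2 1.42.0, its size factors, other filters, no plate term, probes summed per gene, only the wells of a comparison, plate sums, wells as samples, keeping the flagged wells, and leaving out each plate. A further 3 alternatives were added after seeing the data: a common dispersion, a covariate for the main axis of variation among DMSO wells, and leaving out wells under 2000000 counts.

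The fit was tested on simulated counts with the depths and spread of these wells. Changes were made only in probes with a mean count of at least 20 in DMSO wells, so recovery at lower counts is not known. For E2 without S9, 71% of 2-fold and 96% of 4-fold changes were called, against 76% and 97% with DESeq2. With 18822 probes tested, the changed ones included, there were 6 false calls, against 22 with DESeq2. Here edgeR was fitted to all 190 wells and DESeq2 to the 24 DMSO and E2 wells without S9. These values thus do not compare the tools on the same wells. Probes were drawn independently of each other, so variation shared by the probes of a well was absent. These false calls are thus no measure of those in the real wells. The E2 difference between conditions recovered 42% and 87%, stilbene at 100 µM with S9 31% and 82%, and S9 in DMSO wells 74% and 97%. For S9 in DMSO wells the simulated plates shared 1 expression profile, so variation between plates was absent. The 74% and 97% may thus overstate the recovery in real plates. The joint test over 8 concentrations recovered 0% of 2-fold and 35% of 4-fold changes made at a single concentration. Figures and the probe search used Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6. No 2 wells among the 426 pairs within groups had identical counts. The p-values throughout measure spread between these wells and plates of 1 cell line.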

Results

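Expression was measured in 192 wells of VM7Luc4E2 cells, 96 under lids with rat liver S9 and 96 under lids with water. Each condition had 15 DMSO wells, 9 wells of E2 at 0.0001 µM and 3 wells of each of 8 concentrations of trans-stilbene, ethylparaben and daidzein, spread over 3 plates. Total counts had a median of 9009712 per well with S9 (1536834 to 12268308) and 7464113 without S9 (955507 to 11503284). The DMSO and E2 wells had medians of 8858879 and 7530382. Genes that met the rule for named genes moved the same way in every plate of a comparison with DMSO. For S9 in DMSO wells and the joint tests, their plates with S9 all lay above or all below those without S9. Other genes, and the effects per condition in a joint test, need not have the same sign in every plate. Plates 1 and 2 of each condition had the same layout, so these 2 do not tell a treatment from a well position. Layouts differed between the conditions, so well position may contribute to any difference between them.

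The first question was how the cells responded to E2, the natural ER agonist, without metabolic enzymes. GREB1, an ER target that promotes growth, rose by 3.52 ± 0.19 (SE, log2), from 17.0 ± 8.19 CPM (SD, n = 15 wells) to 187 ± 41.1 CPM (n = 9), with an edgeR adjusted p of 1.85e-35. Its probe lies in the 5' UTR, exon 1, on chromosome 2 at 11556565 to 11556614 (GRCh38). TFF1, a secreted trefoil factor induced by estrogen (chromosome 21, 42362486 to 42363294, coding exons 2 to 3), rose by 1.91 ± 0.11 from 376 to 1408 CPM. CALCR, the calcitonin receptor, rose by 2.35 ± 0.20 and the cell-cycle phosphatase CDC25A by 2.13 ± 0.33. The proliferation marker MKI67 rose by 0.96 ± 0.09, TYMS, which makes thymidylate, by 1.03 ± 0.08, and the replication helicase subunit MCM5 by 1.01 ± 0.12. The growth factor receptor gene ERBB2 fell by 0.71 ± 0.07, the interleukin receptor IL1R1 by 1.62 ± 0.24 and the cell-surface antigen PSCA by 1.61 ± 0.13. NQO1, a quinone reductase, fell by 0.72 ± 0.12 and the retinaldehyde dehydrogenase ALDH1A3 by 1.62 ± 0.21.

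In that comparison edgeR called 1742 of 20435 probes, 937 up and 805 down, and DESeq2 called 2130, of which 1697 were shared. With a covariate for the main axis of variation among DMSO wells, edgeR called 1900, and 1441 of the 1742 were among them. The named set also held HS3ST3A1, SCNN1B, TMEM201, SLC47A1, HS3ST3B1 and COL21A1 among those up, by 2.15 to 2.62, and ATP6V0A4, RIPOR3, CCL17, P2RX2, PLAU, PSG3 and CHRD among those down, by -2.38 to -1.58. Of the list of 30 estrogen-induced genes, 24 were called up (24 adjusted over the list alone), with a median of 1.17 (camera adjusted p = 4.00e-36). All 10 estrogen-repressed genes were called down (10 adjusted over the list alone, median -0.72, p = 2.52e-22). Mitosis had 12 of 14 genes up (12 adjusted over the list alone, p = 2.37e-24) and DNA replication 13 of 15 up (14 adjusted over the list alone, p = 7.25e-29). AhR targets had 4 down and 1 up (p = 0.0155). These 5 calls held with an estimated correlation, at adjusted p of 7.55e-20, 1.38e-11, 5.83e-09, 6.74e-09 and 0.0478. The other lists were not called by camera. Their adjusted p was 0.382 for NRF2, 0.944 for ATF4, 0.713 for endoplasmic reticulum stress, 0.831 for heat shock, 0.14 for p53, 0.58 for cholesterol synthesis, 0.499 for metallothioneins and 0.762 for hypoxia and glycolysis. It was 0.831 for interferon, 0.998 for NF-kB, 0.694 for glucocorticoid targets, 0.58 for luminal, 0.382 for basal, 0.801 for hepatocyte, 0.899 for fibroblast and 0.944 for immune markers. ATF4, glucocorticoid and fibroblast lists had a median of the opposite sign to the test, and hypoxia and interferon a mean of the opposite sign. Leaving out plate 1 or plate 2 without S9 lowered the count to 970 and 1087.

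With S9, E2 raised 3 genes past the threshold. CA12, a carbonic anhydrase induced by estrogen, rose by 0.76 ± 0.13 (SE, log2; edgeR adjusted p = 0.000993), from 119 ± 23.3 CPM (n = 15) to 203 ± 69.5 CPM (n = 9). TSKU, a secreted proteoglycan, rose by 0.76 ± 0.15 (p = 0.00772) and TPD52L1, linked to proliferation, by 0.48 ± 0.10 (p = 0.0207). GREB1 (0.72 ± 0.19, p = 0.401) and TFF1 (0.46 ± 0.11, p = 0.332) lay above DMSO in 3 of 3 plates without passing. MKI67 (0.06 ± 0.10, p = 0.899, up in 1 of 3 plates) and ERBB2 (-0.01 ± 0.07, p = 0.994) did not pass either. The other tool, DESeq2, also called 3 probes, and 1336 had an unadjusted p under 0.05. Without plate 1 or plate 2 with S9 edgeR called 0 probes, and without plate 3 it called 4. Of the 30 estrogen-induced genes 1 was called, and 7 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 3.15e-06, 0.000183 with an estimated correlation). Heat shock (p = 0.00685) and mitosis (p = 0.00837, 0 members called and 3 adjusted over the list alone) lost their calls with an estimated correlation (adjusted p = 0.0992 and 0.288).

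The test of the difference asked whether the E2 effect itself differed between plates with S9 and without S9, whose layouts also differed. It was lower with S9 by -2.79 ± 0.28 (SE, log2) for GREB1 (edgeR adjusted p = 4.62e-14), -1.45 ± 0.16 for TFF1 (8.14e-12) and -1.77 ± 0.29 for CALCR (4.76e-06). XBP1, a transcription factor of the secretory pathway that E2 raised by 1.34 ± 0.25 without S9, had a difference of -1.56 ± 0.37 (p = 0.0032). MKI67 (-0.90 ± 0.14), TYMS (-0.94 ± 0.12) and MCM5 (-0.96 ± 0.17) also had weaker effects with S9. Repressed genes moved the other way, with 0.70 ± 0.10 for ERBB2 (p = 1.78e-07), 1.43 ± 0.32 for IL1R1 and 1.49 ± 0.18 for PSCA. NQO1, which fell without S9, had a difference of 0.92 ± 0.17 (p = 4.64e-05). CA12 (-0.46 ± 0.19, p = 0.169) and TSKU (-0.63 ± 0.21, p = 0.0736) did not pass. In all, 742 probes differed, 341 higher and 401 lower, and 710 of them were among 1209 called by DESeq2. The count was 346 and 421 without plates 1 and 2 without S9, 397 without plate 1 with S9, and 344 without plate 2 with S9. Among estrogen-induced genes 11 were lower (19 adjusted over the list alone, median -1.03), and among repressed genes 8 were higher. Mitosis had 8 lower (10 adjusted over the list alone) and DNA replication 9 (14 adjusted over the list alone). For AhR targets 2 were higher (4 adjusted over the list alone), and camera called all 5 lists with either correlation.

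**Figure D1:**
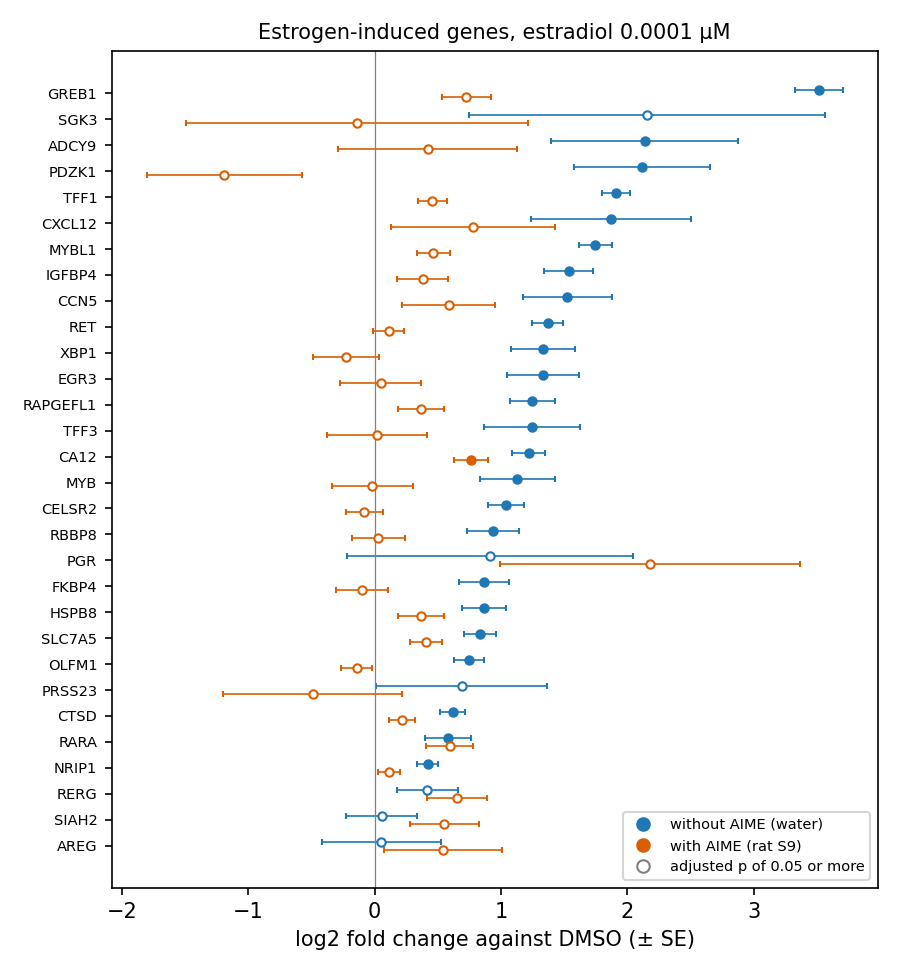
Log2 change against DMSO (with SE) of the 30 estrogen-induced genes in cells exposed to 0.0001 µM E2, with AIME (rat S9) and without AIME (water); open circles did not pass. GREB1 reached 3.52 without S9 and 0.72 with S9.

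The ER score, which averages the estrogen-induced genes, was 1.15 ± 0.17 (SD, n = 3 plates) for E2 without S9 and 0.22 ± 0.03 (n = 3) with S9, which is 18.7% of the former. Both passed an exact permutation test, at p = 5.7e-06, the smallest it can give, and p = 3.42e-05. The difference of -0.94 (SE 0.10) had an exact permutation p of 0.1, the smallest that 3 plates against 3 allow. In DMSO wells the mean score was 3.73 ± 0.04 with S9 and 3.72 ± 0.07 without S9 (SD, n = 3 plates).

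**Figure D2:**
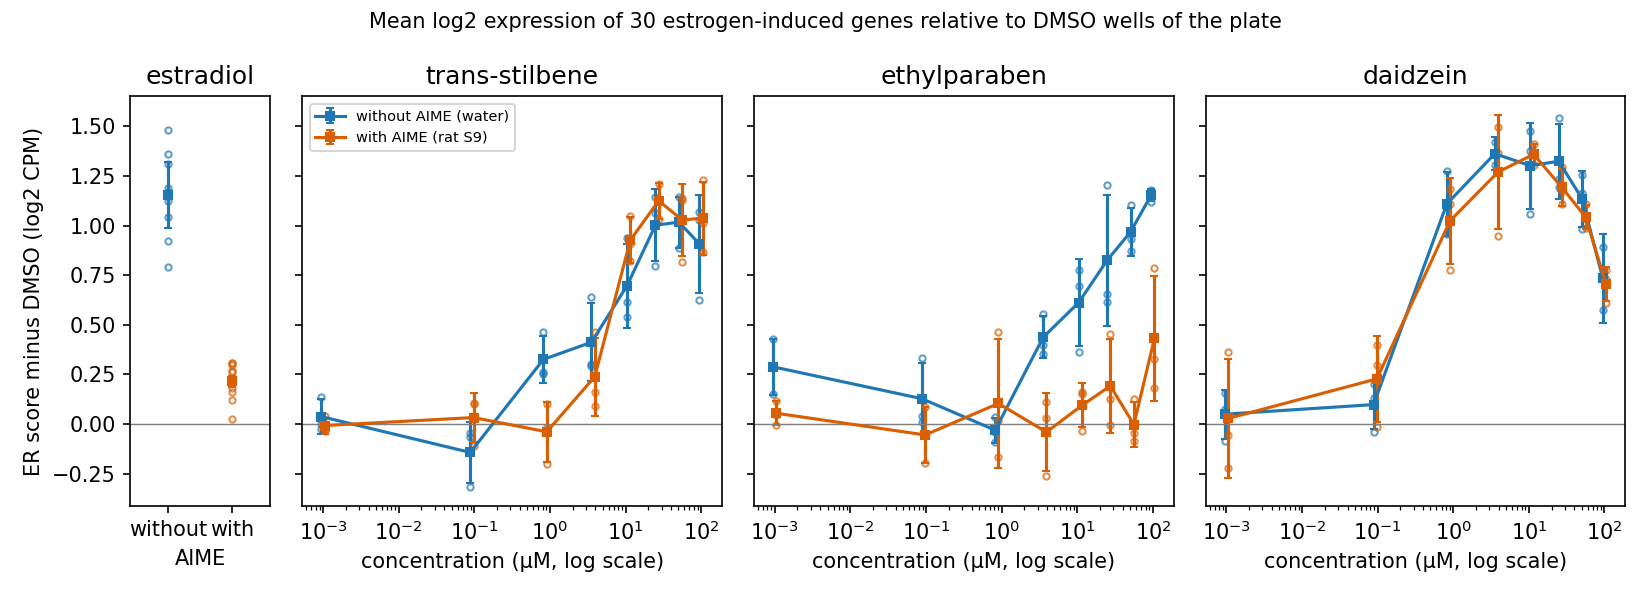
ER score (log2 relative to the DMSO wells of the plate) against concentration (µM, log axis) for E2 and the 3 chemicals, with AIME (rat S9) and without AIME (water); circles are wells, squares means and error bars the SD over plates. E2 reached 1.15 without S9 and 0.22 with S9, while daidzein at 11 µM reached 1.30 and 1.36.

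S9 against water in DMSO wells compared the conditions without a test chemical. Each plate held 1 condition, so an effect of S9 cannot be told apart from other differences between plates here. DHRS3, which reduces retinaldehyde (chromosome 1, 12579349 to 12579398, coding exon 3), was higher with S9 by 3.24 ± 0.26 (SE, log2; edgeR adjusted p = 5.42e-05), at 18.1 ± 5.12 against 1.99 ± 1.26 CPM (SD, n = 15 wells on 3 plates in both). BDKRB2, the bradykinin receptor B2, was higher by 2.95 ± 0.15 at 168 against 21.8 CPM. TGFBI, an extracellular matrix protein, was higher by 2.22 ± 0.20 and the immune checkpoint ligand VTCN1 by 2.24 ± 0.23. The patterning genes HOXA1 (2.92 ± 0.45) and HOXA5 (2.78 ± 0.43) and the retinol transporter STRA6 (2.31 ± 0.27) were higher too. The S-phase genes TYMS (0.89 ± 0.15) and MCM5 (0.78 ± 0.14) and the proliferation marker MKI67 (0.78 ± 0.17, p = 0.0275) were higher with S9. ANXA1, a phospholipid-binding protein, fell by 2.01 ± 0.24, from 29.8 ± 14.1 to 7.44 ± 3.08 CPM, and the early-response factor EGR3 fell by 1.70 ± 0.31. TFF1 (1.14 ± 0.28, p = 0.0707) and GREB1 (-0.54 ± 0.29, p = 0.496) did not pass.

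In that comparison edgeR called 428 of 16351 probes, 296 higher and 132 lower with S9, and DESeq2 called 721. ANG, ADORA1 and SERPINA3 were also named among those higher, and FOXI1, LY6G6C, FAM25C, THEG, XG, AMIGO2 and CCN3 among those lower. The probes of UGT1A8 and UGT1A10, lower by -2.10 and -2.01, match several genes of the UGT1A cluster. DNA replication had 12 of 15 genes higher (13 adjusted over the list alone, median 0.87, camera adjusted p = 6.04e-20, fry adjusted p = 0.0352) and mitosis 3 of 14 (4 adjusted over the list alone, p = 2.90e-07). Camera also called estrogen-repressed genes (2 lower, p = 0.0256), NRF2 targets and cholesterol synthesis, both lower at p = 0.0495. None of these calls held with an estimated correlation (adjusted p = 0.302 for DNA replication and 0.767 for the others). Estrogen-induced genes had 3 higher and 2 lower (p = 0.957). Hepatocyte markers had 0 called by edgeR, a median of -0.15 and a camera test of the opposite sign (p = 0.804). Without plate 2 without S9 the count was 218. Without plates 1, 2 and 3 with S9 it was 267, 135 and 153.

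Trans-stilbene, a parent hydrocarbon without the hydroxyl groups that bind ER, was tested for activity that depends on metabolism. At 100 µM GREB1 rose alike in both conditions, by 3.07 ± 0.24 without S9 (SE, log2; 137 ± 12.3 CPM, n = 3) and 3.07 ± 0.24 with S9 (99.6 ± 18.3 CPM, n = 3). TFF1 rose by 1.95 ± 0.15 and 1.69 ± 0.15, and TSKU by 1.63 ± 0.20 and 2.58 ± 0.19. With S9 the oxidative stress genes rose: GCLM, for glutathione synthesis, by 1.57 ± 0.14 (edgeR adjusted p = 9.44e-18), thioredoxin reductase TXNRD1 by 1.29 ± 0.17, G6PD by 1.38 ± 0.20 and heme oxygenase HMOX1 by 1.26 ± 0.28. NQO1 (chromosome 16, 69711156 to 69711205, coding exon 6) rose by 0.73 ± 0.17 with S9 (p = 0.00261), to 3397 ± 538 CPM, against -0.03 ± 0.18 without S9 (p = 0.98). Without S9 GCLM (0.92 ± 0.15) and TXNRD1 (0.67 ± 0.18, p = 0.02) rose. IL1R1 fell by 1.78 ± 0.39 and PSCA by 1.43 ± 0.21 without S9, and VTCN1 fell by 2.33 ± 0.28 with S9.

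At 100 µM edgeR called 360 probes without S9 (208 up, 152 down) and 479 with S9 (242 up, 237 down), and DESeq2 called 416 and 686. Without plates 1 and 2 the counts were 159 and 142 without S9. With S9 they were 209, 160 and 280 without plates 1, 2 and 3. Also named without S9 were SCNN1B, SLC47A1, CYP24A1, HS3ST3A1, IGSF1 and NPR2 (up) and SEMA5A, PTPRN2, GDPD2, PIP5K1B, SVOPL, P2RX2, ELF5 and APOD (down). USP17L30, USP17L23 and GGT6 passed too, but GGT6 had 90.4 ± 138 CPM over 3 wells. With S9 SLC7A11 (2.99 ± 0.79), NKAIN1, CNTD2, UGT1A8, GPR65, NXNL2, AMZ1 and CYP26B1 rose, and HMGCS2, TINAGL1, PKP1, C13orf46, HOPX, PALM2, VGLL1, ENC1 and PIK3R3 fell. NRF2 targets had 13 of 19 called with S9 (13 adjusted over the list alone, median 1.30, camera adjusted p = 7.17e-31) and 2 without S9 (8 adjusted over the list alone, p = 0.00142). Estrogen-induced genes had 10 (16 adjusted over the list alone) without S9 and 14 (17 adjusted over the list alone) with S9. ATF4 targets had 3 without S9 (p = 0.00892) and 6 with S9 (p = 1.25e-12), and p53 targets had 4 with S9 (p = 3.82e-06). DNA replication had 10 and 1 called. With an estimated correlation ATF4 without S9 was lost (adjusted p = 0.0718), as were interferon (p = 0.0384, then adjusted p = 0.353) and NF-kB (p = 0.0195, then adjusted p = 0.0593) with S9.

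The joint test asked whether the stilbene effect differed between plates with S9 and without S9 at any of the 8 concentrations. Averaged over them, NQO1 was at 0.46 ± 0.03 (SD, n = 3 plates) with S9 and -0.17 ± 0.22 (n = 3) without S9, with an edgeR adjusted p of 1.32e-06. GCLM was at 0.80 ± 0.20 and 0.32 ± 0.08 (p = 3.24e-09), TXNRD1 at 0.63 ± 0.15 and 0.13 ± 0.19 (p = 0.000787) and the iron store FTH1 at 0.74 ± 0.06 and -0.00 ± 0.23 (p = 0.0229). DHRS2, a short-chain dehydrogenase, went from 0.69 ± 0.31 without S9 to -0.74 ± 0.15 with S9 (p = 1.59e-13). Replication-dependent histone genes differed the same way, with H3C12 at 0.41 ± 0.16 without S9 and -0.58 ± 0.20 with S9 (p = 2.89e-11). H1-5, H1-3, H2BC13, H2BC14, H2BC11, H2BC8 and H2AC15 followed, as did H4C15, whose probe matches 2 genes. UGT1A10, HBEGF, G6PD, TRIM16L, ME1 and TPD52L1 were also higher with S9. The test called 69 probes, 19 higher and 50 lower, and DESeq2 called 106. Without plate 2 without S9 the count was 35 and without plate 3 it was 104, and without plate 2 with S9 it was 40. Camera called NRF2 targets higher (7 members, 11 adjusted over the list alone, p = 2.23e-16) and mitosis lower (p = 2.30e-10), and also DNA replication lower and p53 targets higher, with either correlation. AhR (0.0451), ATF4 (0.0258) and interferon (0.00944) passed with the preset one only, with adjusted p = 0.14, 0.156 and 0.297 with an estimated correlation. At 100 µM alone 2 probes passed, and NQO1 (0.76 ± 0.25, p = 0.744) did not.

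**Figure D3:**
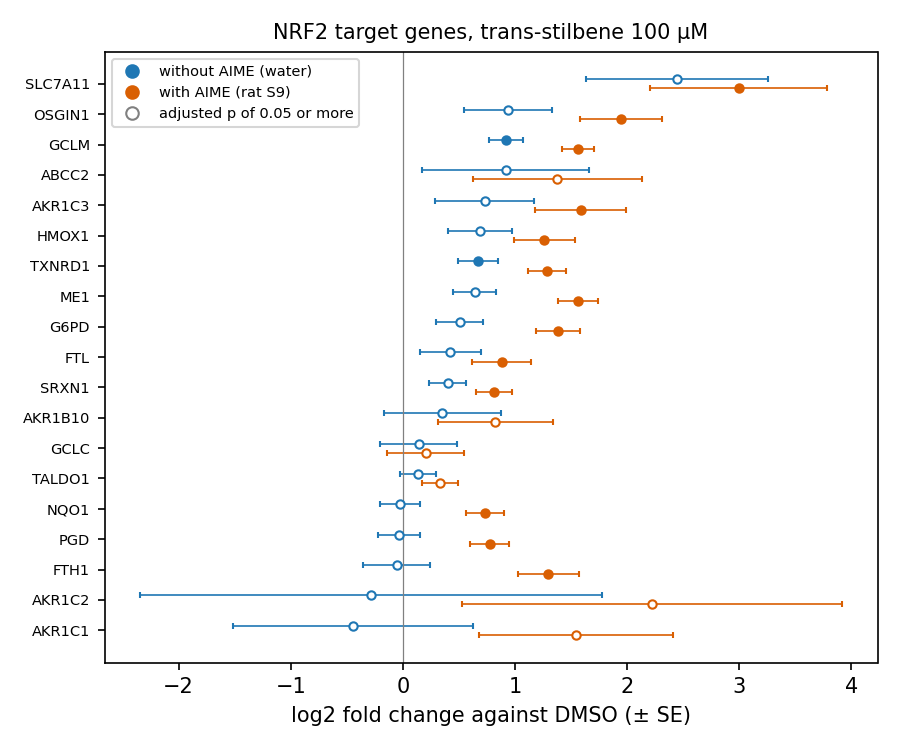
Log2 change against DMSO (with SE) of the NRF2 target genes in cells exposed to 100 µM trans-stilbene, with AIME (rat S9) and without AIME (water); open circles did not pass. GCLM reached 1.57 with S9 and 0.92 without S9.

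The ER score of stilbene was 0.33 ± 0.12 (SD, n = 3 plates) without S9 at 0.865 µM and -0.04 ± 0.15 with S9 (exact permutation test of the difference, p = 0.1, the smallest possible). At 26.1 µM it was 1.00 ± 0.18 and 1.12 ± 0.09, and at 100 µM 0.91 ± 0.25 and 1.04 ± 0.18, a difference of 0.13 (SE 0.18, exact permutation p = 0.6). The lowest concentration from which that and every higher one had at least 10 called probes was 11 µM in both conditions, with 379 without S9 and 212 with S9. The count at 11 µM was 66, 180 and 1105 without plates 1, 2 and 3 without S9, and 83, 72 and 36 without plates 1, 2 and 3 with S9. From 0.001 to 3.73 µM edgeR called 0 to 3 probes without S9 (708 to 1458 at an unadjusted p under 0.05; DESeq2 called 3 to 20). With S9 it called 0 (396 to 620 at an unadjusted p under 0.05; DESeq2 called 0 to 5).

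Ethylparaben, a preservative and weak estrogen that esterases cleave to 4-hydroxybenzoic acid, was tested for loss of activity. At 100 µM without S9 GREB1 rose by 3.75 ± 0.23 (SE, log2), to 216 ± 8.81 CPM (n = 3; edgeR adjusted p = 1.29e-29), TFF1 by 1.96 ± 0.15, CALCR by 2.42 ± 0.26 and MKI67 by 1.08 ± 0.13. ERBB2 fell by 0.73 ± 0.11, ALDH1A3 by 1.67 ± 0.34 and PSCA by 1.34 ± 0.21. With S9 GREB1 rose by 1.33 ± 0.27 (edgeR adjusted p = 0.0119), to 29.9 ± 13.5 CPM (n = 3). CA12 rose by 1.00 ± 0.19 (p = 0.00754) and MYOF, a membrane repair protein, by 0.53 ± 0.10 (p = 0.00782). TFF1 (0.67 ± 0.16, p = 0.239, up in 3 of 3 plates) and MKI67 (-0.01 ± 0.14) did not pass with S9.

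At 100 µM edgeR called 535 probes without S9 (278 up, 257 down) and 3 with S9 (512 at an unadjusted p under 0.05), and DESeq2 called 853 and 8. Without S9 the count was 312, 175 and 286 without plates 1, 2 and 3. With S9 it was 0, 0 and 5 without plates 1, 2 and 3. Also named without S9 were SPINK4, CSTF2T, SCNN1B, HS3ST3A1, TEX14, PLIN5, HS3ST3B1 and SDK2 (up), and ATP6V0A4, CCL22, LYPD1, CAPZA1, MEIG1, ESRP2, UPK2, RNF224, AQP3 and RARG (down). Estrogen-induced genes had 14 of 30 called without S9 (18 adjusted over the list alone, median 1.11, camera adjusted p = 1.50e-30). With S9 they had 2 (6 adjusted over the list alone, median 0.33, p = 4.29e-10), and both calls held with an estimated correlation. Repressed genes had 4 without S9 (9 adjusted over the list alone), and 0 with S9 (also 0 adjusted over the list alone; p = 0.0102, adjusted p = 0.106 with an estimated correlation). Mitosis had 8 (10 adjusted over the list alone, p = 2.39e-16) and DNA replication 4 (8 adjusted over the list alone, p = 4.72e-10) without S9, and neither passed with S9 (both p = 0.622).

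Averaged over the 8 concentrations, the ethylparaben effect on GREB1 was 0.18 ± 0.12 (SD, n = 3 plates) with S9 and 1.95 ± 0.60 (n = 3) without S9, with an edgeR adjusted p of 2.94e-10 in the joint test of the difference. TFF1 was at 0.25 ± 0.03 and 0.95 ± 0.11 (p = 1.02e-06), and MKI67 at 0.04 ± 0.13 and 0.60 ± 0.21 (p = 0.00151). SPINK4, CHAC1, DHRS2, PBK, MYBL1, CLSPN and TPD52L1 had lower effects with S9, and PSCA, SAT1, MYO6 and ERBB2 (-0.07 ± 0.01 against -0.26 ± 0.12) had higher ones. The joint test called 28 probes, 4 higher and 24 lower, and DESeq2 called 53. The count was 3 and 4 without plates 1 and 2 without S9, and 3, 6 and 6 without plates 1, 2 and 3 with S9. Estrogen-induced genes had 3 called (10 adjusted over the list alone, camera p = 3.41e-16). Repressed genes (p = 0.0015), mitosis (p = 8.26e-12) and DNA replication (p = 2.91e-11) differed with either correlation.

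The ER score of ethylparaben was 0.44 ± 0.11 (SD, n = 3 plates) at 3.73 µM, 0.97 ± 0.12 at 53.5 µM and 1.15 ± 0.03 at 100 µM without S9. With S9 it was -0.04 ± 0.20, -0.00 ± 0.11 and 0.43 ± 0.32. Differences at 3.73 to 100 µM were -0.97 to -0.48, each with an exact permutation p of 0.1, the smallest possible. At 0.001 µM the score without S9 was 0.29 ± 0.14 (exact permutation adjusted p = 0.00823), with a difference of -0.23 (exact permutation p = 0.1). At 0.093 and 0.865 µM without S9 it was 0.13 ± 0.18 and -0.03 ± 0.06 (exact permutation adjusted p = 0.258 and 0.729). The lowest concentration from which that and every higher one had at least 10 called probes was 11 µM without S9, with 12 probes. It was 26.1 µM when any 1 of the 6 plates was left out, with 6, 2 and 6 probes at 11 µM without plates 1, 2 and 3 without S9, and 9, 7 and 8 without plates 1, 2 and 3 with S9. With S9 36 probes were called at 0.093 µM (DESeq2 136), 0 without plate 1 or 2 with S9, 208 without plate 3 with S9 and 122 without plate 1 without S9. At 0.001 µM and from 0.865 to 53.5 µM edgeR called 0 with S9, against 498 to 1848 at an unadjusted p under 0.05 and 0 to 8 by DESeq2. With 3 at 100 µM, no concentration with S9 met the criterion.

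**Figure D4:**
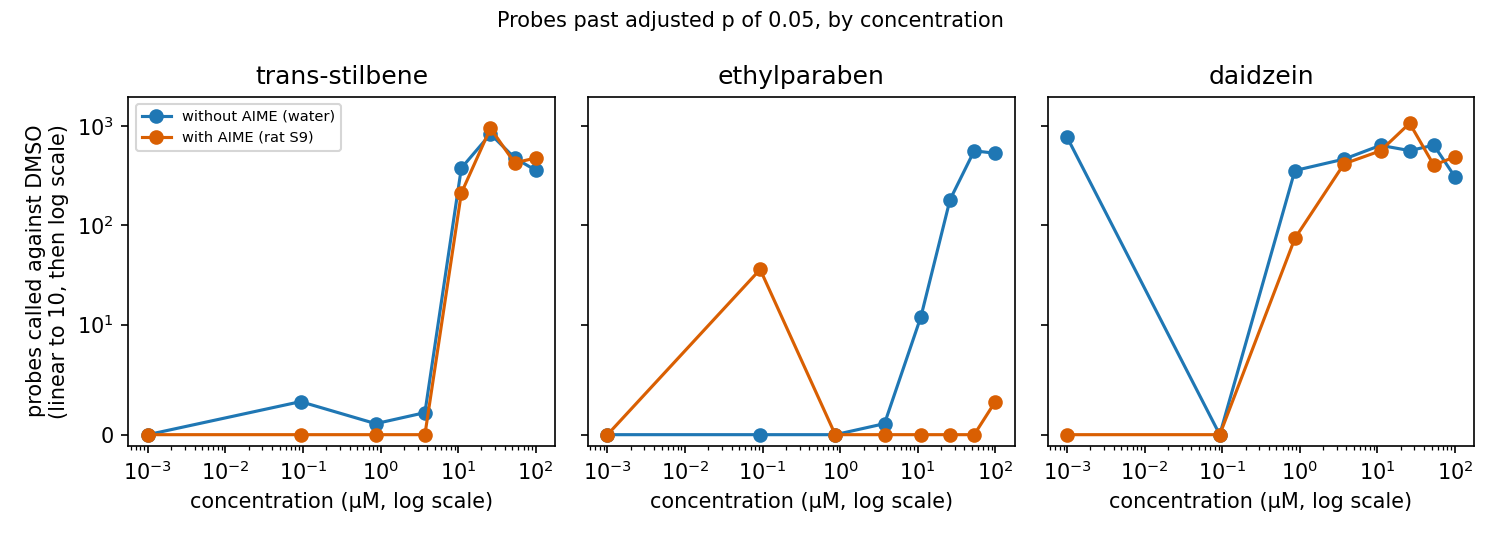
Number of called probes (adjusted p under 0.05) (linear to 10, then on a log scale) against concentration (µM, log axis) for each chemical, with AIME (rat S9) and without AIME (water). At 53.5 µM ethylparaben had 566 without S9 and 0 with S9 (916 at an unadjusted p under 0.05; 4 by DESeq2).

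Daidzein, an isoflavone that binds ER, was the chemical tested for activity that metabolism leaves in place. At 100 µM TFF1 rose by 2.27 ± 0.17 without S9 (SE, log2; 2018 ± 658 CPM, n = 2) and 2.25 ± 0.15 with S9 (3781 ± 1231 CPM, n = 3), and GREB1 by 2.40 ± 0.28 and 2.85 ± 0.24. The AhR-induced TIPARP rose by 0.99 ± 0.18 and 1.12 ± 0.15. Without S9 the amino acid stress genes PHGDH (1.9 ± 0.27), CHAC1 (1.72 ± 0.45) and DDIT3 (1.09 ± 0.22) and the chaperone HSPA5 (0.94 ± 0.17) rose, while with S9 PHGDH (-0.39 ± 0.27, p = 0.717) and DDIT3 (-0.20 ± 0.20, p = 0.825) did not pass. At this concentration the difference was -2.29 ± 0.41 for PHGDH (edgeR adjusted p = 0.00138) and -1.92 ± 0.65 for CHAC1 (p = 0.88). LDLR, the LDL receptor, rose by 0.51 ± 0.12 with S9. The epithelial differentiation genes CSTA and ZNF750 fell by 3.66 ± 0.56 and 3.90 ± 0.65 without S9. SLC9A4, a sodium-proton exchanger, fell by 2.59 ± 0.41 with S9.

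At 100 µM edgeR called 310 probes without S9 (124 up, 186 down) and 492 with S9 (177 up, 315 down), and DESeq2 called 511 and 648. Without plates 2 and 3 without S9 the former was 131 and 91, each from a lone well assumed to vary like the others. The latter was 167, 214 and 227 without plates 1, 2 and 3 with S9. Also named without S9 were PPFIA4, DYRK3, NGFR, BEX5, FAM126A and TMEM191B (up), and S100A8, PLAAT4, PLEKHS1, SYNGR1, TINAGL1, PSG9, HOPX and ARHGEF4 (down). With S9 PPM1K, NXNL2, BEX5, TSKU, GM2A, STK17A, SLC27A5 and HS3ST3A1 rose, and GBP3, PLAAT2, HMGCS2, RNASE4, CCL22, ACOX2, TMEM40, TINAGL1 and VGLL1 fell. Estrogen-induced genes had 5 called without S9 (6 up and 1 down adjusted over the list alone, camera adjusted p = 6.52e-11) and 8 with S9 (12 adjusted over the list alone, p = 3.83e-16). Cholesterol synthesis had 3 in both (5 adjusted over the list alone, p = 2.40e-06 and 0.000342). ATF4 targets had 6 called without S9 (9 up and 1 down adjusted over the list alone, p = 7.27e-07), and with S9 the list did not pass (p = 0.706). Endoplasmic reticulum stress passed without S9 (1 called, 2 adjusted over the list alone, p = 3.73e-05). With an estimated correlation mitosis was lost in both (p = 0.00121 and 0.0473, then adjusted p = 0.0728 and 0.327), as was interferon with S9 (p = 0.000197, then adjusted p = 0.145).

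Averaged over the concentrations, of which plate 1 without S9 lacked 3.73 and 100 µM, the daidzein effect on the metal-binding MT2A was -0.14 ± 0.21 (SD, n = 3 plates) with S9 and 0.80 ± 0.30 (n = 3) without S9 (edgeR adjusted p = 0.00102 in the joint test). PHGDH was at -0.16 ± 0.04 and 0.42 ± 0.05 (p = 0.00513) and the keratin KRT15 at 0.80 ± 0.19 and 0.24 ± 0.15 (p = 0.00169). The cell-cycle genes NCAPG (0.22 ± 0.14 and 0.77 ± 0.30) and SPC24 and the histone genes H1-5, H1-3 and H4C1 had lower effects with S9, as did RPL7, TP73 and IQGAP3. IGHE and PLA2G4C had higher ones. The joint test called 32 probes, 7 higher and 25 lower, and DESeq2 called 109. The count was 3 without plate 1 without S9, and 3, 0 and 6 without plates 1, 2 and 3 with S9. Mitosis (1 called, 7 adjusted over the list alone, camera p = 1.75e-14) and DNA replication (5 called, 11 adjusted over the list alone, p = 5.76e-08) were lower with either correlation. Endoplasmic reticulum stress passed with the preset one only (p = 0.0351, adjusted p = 0.0657 with an estimated correlation). Estrogen-induced genes did not differ past the threshold (p = 0.888).

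The ER score of daidzein was 1.11 ± 0.16 (SD, n = 3 plates) without S9 and 1.02 ± 0.22 (n = 3) with S9 at 0.865 µM, where edgeR called 358 and 74 probes. The former count was 149 and 154 without plates 2 and 3 without S9, and the latter 16 and 20 without plates 1 and 2 with S9. At 11 µM the score was 1.30 ± 0.22 and 1.36 ± 0.05, and at 100 µM 0.73 ± 0.22 (n = 2) and 0.70 ± 0.09 (n = 3). The differences ran from -0.13 to 0.13 with exact permutation p of 0.4 to 1. Without S9 776 probes were called at 0.001 µM (230 up, 546 down), where the score was 0.05 ± 0.12. That count was 51, 364 and 0 without plates 1, 2 and 3 without S9, and 447 without plate 2 with S9. At 0.093 µM edgeR called 0 in both conditions, where DESeq2 called 7 without S9 and 3 with S9 and 944 and 720 had an unadjusted p under 0.05. The score there was 0.10 ± 0.12 without S9 (exact permutation adjusted p = 0.342) and 0.23 ± 0.22 with S9 (exact permutation adjusted p = 0.0307). It was up in 2 of 3 plates in both. The lowest concentration from which that and every higher one had at least 10 called probes was 0.865 µM in both.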

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

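The tests of daidzein responsiveness, of the DNA replication baseline, of depth and of the DMSO axis below were chosen after the result was seen, and the other tests before. GREB1, TFF1, MKI67 and the other genes of the estrogen response stood out because the E2 effect differed between wells with S9 and without S9, with 742 called probes (341 higher, 401 lower). The ER score of E2 with S9 was 18.7% of that without S9. GREB1 moved by 3.52 ± 0.19 without S9 and 0.72 ± 0.19 with S9 (log2, SE).

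This pattern was set against explanations other than loss of E2 in the medium. Cells with a lower largest response to any ER agonist would have a weaker daidzein effect with S9, but its mean ER score from 0.865 to 53.5 µM was 94.5% of that without S9, which argues against it. These scores lie on a plateau, so cells that needed more agonist for the same response stay open. At 0.093 µM, below the plateau, the daidzein scores differed by 0.1295 (SE 0.14) but were too small to decide. At 0.865 µM edgeR called 358 probes without S9 (149 and 154 without plates 2 and 3 without S9) and 74 with S9 (16 and 20 without plates 1 and 2 with S9). The difference there had 0 probes called by edgeR (707 at an unadjusted p under 0.05; DESeq2 not run on it), and the ER scores differed by -0.09 (exact permutation p = 0.7). Lower depth is argued against as well, since the median total count of DMSO and E2 wells with S9 was 117.6% of that without S9. Along the main axis of variation among DMSO wells, the E2 wells had a mean of -0.56 without S9 and 0.40 with S9. With this axis as a covariate the E2 difference had 658 called probes, and 458 of the 742 were among them. Variation between wells, which followed position on plates whose layouts differed between conditions, may thus lie behind part of the 742 calls. S9 did not raise the estrogen-induced genes as a set in DMSO wells beforehand, as their ER score differed by 0.003137 between conditions. For the replication genes the baseline did rise. With S9 the DNA replication genes were higher in DMSO wells by a median of 0.87, which is 89.72% of their median E2 effect without S9. As a list they passed with the preset correlation (camera adjusted p = 6.04e-20) but not with an estimated one (adjusted p = 0.302), while 12 of 15 members and MKI67 (0.78 ± 0.17, SE) were called. A raised baseline is thus a candidate explanation for the smaller E2 effect on these genes. Conversion of E2 by S9 enzymes during conditioning may explain the loss in the estrogen-induced genes, but no E2 level was analysed here and this stays untested.

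The stilbene effect also differed between conditions, with 69 called probes, where NQO1 and GCLM were higher and DHRS2 and H3C12 lower with S9. The ethylparaben effect differed in 28 probes, led by GREB1 and TFF1, and the daidzein effect in 32, among them MT2A, PHGDH and NCAPG. Loss of ethylparaben to S9 esterases and formation of reactive stilbene products are hypotheses. Neither was tested, as no level of a chemical or its products was analysed here.

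Other splits of the samples were counted for each comparison, refitted on its own wells. For E2 without S9 the real split called 898 probes and was the only 1 of 100 with as many, with 361 as the highest other, so chance can be excluded. For E2 with S9 edgeR called 0 in the refit (with all wells 3, DESeq2 also 3, and 1336 at an unadjusted p under 0.05), so all 100 splits, with 0 as the highest other, had to match it and the count decides nothing. Its ER score of 0.22 passed an exact permutation test at p = 3.42e-05, up in 3 of 3 plates. Stilbene at 100 µM with S9 called 377 probes, reached by 2 of 60 splits (the real one included) with 781 as the highest other. Daidzein with S9 called 358, reached by 2 of 60 with 1377 as the highest other. Both shares met the bound of under 0.05 set beforehand against chance, but by a single split. In each, 1 other split called many more probes than the real one, so the number of probes does not exclude chance. Their ER scores, at 1.04 and 0.70, did pass exact permutation tests (adjusted p = 0.00823 for each), up in 3 of 3 plates. The bound was not met for stilbene without S9 (36 probes, 3 of 60, highest other 490), ethylparaben without S9 (103 probes, 3 of 60, highest other 1747) or ethylparaben with S9 (1 probe, 5 of 60, highest other 1258), so chance could not be excluded there either. The ER scores of these last 3 groups, at 0.91, 1.15 and 0.43, also passed exact permutation tests (adjusted p = 0.00823 for each), up in 3 of 3 plates. Splits that called several times the real count point to a structure among the wells beyond their treatment. Splits of the 6 plates are too few for a share under 0.05. S9 in DMSO wells called 428 probes and the differences called 369 for E2, 43 for stilbene, 8 for ethylparaben and 21 for daidzein, each reached by 1 of 10 splits, with 0 as the highest other.

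The 2 wells left out for their flag in the labels carried an estrogen signal that was used only where an alternative kept them. Their ER scores were 0.474 for daidzein at 100 µM and 0.7593 at 3.73 µM, both without S9, above the highest DMSO well at 0.2828. The wells kept had 0.73 ± 0.22 (SD, n = 2 plates) and 1.36 ± 0.08 (n = 2).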

How the results depend on the processing

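The common dispersion, the DMSO axis covariate and the omission of wells under 2000000 counts were added after the data had been seen, and the other alternatives were planned. GREB1, TFF1 and the other named genes kept direction and side of the threshold in 2724 of 3234 values, 509 lost the call and 1 changed sign. That 1 was SYNGR1 for daidzein at 100 µM without S9, at 0.21 (adjusted p = 0.892) with the flagged wells kept, against -3.17, with adjusted p of 0.00333 to 0.892 over its alternatives. Of 221 counts 142 stayed within 1.5 times and 79 moved. For other concentrations 527 of 714 counts stayed. The ER score at 100 µM kept its call in 64 of 66 values, and list calls held in 255 of 273.

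Leaving out 1 plate at a time gave 970 to 1727 probes for E2 without S9, 0 to 4 with S9, 344 to 953 for their difference and 135 to 344 for S9 in DMSO wells. For stilbene it gave 142 to 341 without S9, 160 to 495 with S9 and 35 to 104 for the difference. For ethylparaben it gave 175 to 511, 0 to 5 and 3 to 37, and its lowest concentration without S9 was 26.1 µM each time. For daidzein it gave 91 to 299, 167 to 500 and 0 to 33, with ER scores without S9 of 0.5602 to 0.8908. Omission of a plate leaves fewer wells, and in daidzein without S9 a lone well.

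DESeq2 called 1209 probes for the E2 difference, 721 for S9 in DMSO wells, 853 and 8 for ethylparaben without S9 and with S9, and 511 for daidzein without S9. Its differences were 106 for stilbene, 53 for ethylparaben and 109 for daidzein. Its size factors in edgeR shifted the median by at most 0.03. The share of calls up under the DESeq2 test was 37.8% against 52% for ethylparaben without S9, 37.5% against 100% with S9, 38.2% against 50.5% for stilbene with S9, and for daidzein 25.1% against 40% without S9 and 25.9% against 36.0% with S9. Without the plate term E2 with S9 gave 0 probes and the E2 difference 438. Stilbene gave 214 and 265 with a difference of 20, ethylparaben 286 and 0 with a difference of 2, and daidzein 191 and 294 with a difference of 0.

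Fitting only the wells of a comparison, and so fewer samples, gave 898 probes for E2 without S9, 0 with S9 and 369 for the difference, 36 for stilbene without S9 and 43 for its difference, 103 and 1 for ethylparaben and 8 for its difference, and 38 for daidzein without S9 and 21 for its difference. Counts summed per plate gave 1204 for the E2 difference, and wells taken as samples gave 1152 for S9 in DMSO wells. With the DMSO axis as a covariate the counts were 706 and 875 for stilbene and 633 and 829 for daidzein. They were 109 and 100 for the stilbene and ethylparaben differences and 658 for the E2 difference, with 458 of its 742 calls kept. The lowest stilbene concentration without S9 was then 3.73 µM. Keeping the flagged wells gave 1499 probes for daidzein without S9 and 86 for its difference.

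For ethylparaben without S9 the lowest concentration was 26.1 µM without the plate term, with the flagged wells kept, with only the wells of the comparison, with a common dispersion, or with 50 calls required. No setting gave ethylparaben with S9 a lowest concentration. Apart from fewer samples, the cause was not tested. PGR lay at 0.04 ± 0.07 CPM in DMSO wells with S9 and 0.24 ± 0.40 CPM with E2 (SD), too low for a change to be detectable.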

Other observations

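The histone gene set, the ER score of daidzein at 0.001 µM and the depth of its wells were chosen after seeing the result. The DMSO axis covariate was also added after the data had been seen. The other tests were chosen before their values were seen. Histone genes moved differently with S9 and without S9 under stilbene and E2, from different baselines. In DMSO wells the median difference of 63 such genes, with S9 against without, was 0.96, with 13 called up and 2 down (6 up with no filter, 21 with DESeq2). These 63 genes were chosen by symbol and a mean count of at least 20, so not all need be replication-dependent. Of their probes, 12 match several genes. Under stilbene at 53.5 µM the median change of the 63 genes was 0.95 without S9, with 40 called up. With S9 it was -0.89, with 24 called down. At 100 µM the medians were -0.09 without S9, with 0 called by edgeR and 0 by DESeq2 (1 at an unadjusted p under 0.05), and -1.08 with S9, with 34 called down. E2 moved them by a median of 0.95 without S9, with 50 called up and 2 down, and 0.17 with S9, with 0 called by edgeR and 0 by DESeq2 (2 at an unadjusted p under 0.05). The E2 difference had a median of -0.73, with 23 called lower (7 with no plate term, 9 without plate 2 without S9 and 8 without plate 2 with S9). Daidzein had medians of the same sign in both conditions at 0.865 µM (0.86 without S9 and 0.60 with S9), 3.73 µM (0.97 and 0.43), 11 µM (0.60 and 0.29) and 26.1 µM (0.44 and 0.15). At 100 µM they were -0.11 and -0.31. The signs were opposite at 53.5 µM (0.53 and -0.58), at 0.093 µM (0.31 and -0.51) and at 0.001 µM (-0.41 and 0.19). At 0.093 µM the daidzein difference had a median of -0.85, so such a difference also occurred at a low concentration. Ethylparaben at 53.5 µM had 0.95 and 0.35. At each of the 8 concentrations edgeR called 0 of them for the daidzein difference (0 to 50 at an unadjusted p under 0.05) and 0 for the ethylparaben one (0 to 19 at an unadjusted p under 0.05), and DESeq2 was not run on these differences. Of 47 genes with a lower stilbene effect with S9 and a mean count of at least 20, 39 were histone genes (83.0%), a share from the list that prompted the choice of this set, so a test of it would be void. The stilbene and E2 medians kept their signs with DESeq2, its size factors, the DMSO axis covariate, no filter and no plate term, but with no plate term the stilbene calls at 53.5 µM were 15 up without S9 and 8 down with S9, and 15 down at 100 µM with S9. Without plates 1 and 2 without S9 the 40 calls were 14 and 3, and the median at 100 µM was 0.07 without plate 3 without S9. Without plates 1, 2 and 3 with S9 the 24 calls were 10, 9 and 9, and the 34 were 16 and 20 without plates 2 and 3. In DMSO wells the 13 were 1, 2 and 2 without plates 1, 2 and 3 without S9, and 36, 6 and 8 without plates 1, 2 and 3 with S9.

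Calls at low concentrations without an estrogen response formed a pattern of their own. Daidzein at 0.001 µM without S9 called 776 probes, while its ER score effect was 0.05001, which argues against an estrogenic effect, and low counts are argued against by a median total of 108.2% of that of the DMSO wells. The main axis of variation among DMSO wells held 31.3% of their variance, with YBX1 and COPG2 at one end and PRRT3 and SFPQ at the other. Its loadings followed the GC content of the probes (Spearman's rho across 9864 probes = -0.4465, and probes are not independent). With this axis as a covariate 0.3866% of the daidzein calls stayed, as their median change fell from 0.91 (SE 0.25) to 0.34 (SE 0.17), so variation between wells that also occurs among DMSO wells is a candidate explanation. This axis followed position, with 38 of 48 wells in plate column 9 below 0 against 30 of 142 in columns 10 to 12. The daidzein wells lay at the same position on plates 1 and 2 and at another on plate 3. For ethylparaben at 0.093 µM with S9, 25% of 36 calls stayed, at 0.78 (SE 0.19) against 1.02 (SE 0.24), and this explanation cannot be told apart from an effect of the chemical. An earlier version compared numbers of calls and argued against this explanation. It was replaced by the share of the same probes, which the prediction had named.

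DHRS3, BDKRB2 and the other genes that differed between S9 and water in DMSO wells were set against technical explanations. For rat liver RNA, the hepatocyte markers had a median of -0.1485, with albumin (ALB) at 1.86 ± 3.46 CPM with S9 and 3.63 ± 6.26 without S9 (SD, n = 15). That met the bound set beforehand against rat RNA. However, the probes were searched in human transcripts only. Whether these probes can read rat RNA was not checked, so the markers cannot decide. A difference in depth is argued against, since 93.22% of the calls remained after thinning every plate to the smallest. For GC content Spearman's rho across probes was 0.08945, which met the bound set beforehand against it. But daidzein at 0.001 µM without S9, whose calls were nearly all lost with the GC-linked axis, had a rho of only -0.197. A small rho thus cannot decide on GC content. An effect of S9 on the cells or the medium may lie behind these genes. Rat RNA and GC content stay open, as do differences between plates other than the lids, because each plate held 1 condition.

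DHRS3, HOXA1, HOXA5 and STRA6 are known retinoic acid targets, which raised the hypothesis of retinoid activity in S9 medium. A list of 15 other targets, written after those genes had been seen, had 10 measured members. PLAAT4 was called higher (1.25 ± 0.21, SE; edgeR adjusted p = 0.00549, 13.1 against 5.35 CPM), which is 10% of them, against 1.81% of all probes. That value met the bound set beforehand against the hypothesis, but CRABP2, CYP26B1 and PLAAT4 were the 3 members at 5 CPM or more, and a rule that so few cannot decide was added after the value was seen. CYP26B1 (1.33 ± 0.46, p = 0.187) and CRABP2 (-0.66 ± 0.17, p = 0.0606) did not pass, so the hypothesis stays open.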
